A study of Homo sapiens with 2 samples.

How the data were processed

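Cells of LuCaP96 xenograft tissue were profiled on the 10x Genomics platform, with 1 library titled VEH and 1 titled GSK. Per the labels' protocols, tissue fragments were dissociated with an enzyme mix, red blood cells were lysed and the suspension was strained. The deposited matrices hold raw UMI counts per gene and barcode, per the file headers and the values, for all barcodes and not only for cells. Per the submitters' processing notes, Cell Ranger 6.0.1 and the hg19 genome were used, and the header of the matrices, per the file headers, names Cell Ranger 4. Whether reads of the host were removed is not given in the sources used here. The files list 32738 human genes and no mouse gene, so reads of mouse origin that align to the human genome would be counted as human.

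The matrices list 926955 VEH and 1039809 GSK barcodes. Rows that shared a gene symbol were summed, which concerned 95 symbols. Cells were barcodes with at least the larger of 500 UMIs and an order-of-magnitude limit (the percentile 99 of UMIs over the top 3000 barcodes, divided by 10), at least 300 genes and at most 25% mitochondrial UMIs. The limit came to 3753 UMIs in the VEH and 4471 UMIs in the GSK library. Kept cells held 82.8% of the VEH UMIs (51152684) and 82.7% of the GSK UMIs (55276870). Scrublet, as implemented in scanpy, marked 0.127% and 0.226% of cells as doublets. This is under 0.5%, so the caller was taken not to have worked, no cell was removed, and doublets remain in the data.

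Cells were clustered together with scanpy 1.11.5 on the 2000 most variable genes, 30 components, 15 neighbours and Leiden resolution 0.5, without integration. Y-linked genes and XIST were not removed before clustering, and were left out only of the leading genes. Clusters were to be left out when their 10 leading genes by fold held 2 or more markers of a non-epithelial type. The minimum level of a leading gene had been left open, and was set to 50 CPM after the data were seen. No cluster was then left out. Without a minimum, the cluster led by DCN and LUM (946 VEH and 25 GSK cells) would have been, and the values without it are among the alternatives.

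Counts were summed over the kept cells of each library and divided by their total to give CPM. Ratios of CPM carry exact 95% intervals (conditional binomial, Clopper-Pearson), and log2 ratios were computed on CPM + 1. Shares of cells carry exact Clopper-Pearson intervals. Both kinds cover counting error only. Cells are not replicates, so no p-value, standard error or number of changed genes was computed. For shares and per-cell values each cell was thinned to 6810 UMIs, the percentile 10 of the shallower library, which left out 394 VEH and 149 GSK cells. Empty droplets were barcodes with 10 to 100 UMIs, 69966 in the VEH and 72037 in the GSK library. The most free RNA a cell could hold was set after the data were seen, from thinned cells at or under percentile 33 of the UMIs of every other G2/M gene. It was their mean UMIs of the remaining G2/M genes over those expected from the empty droplets. Percentile 25 was run first, and percentiles 10 and 50 were run as well.

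Fixed gene lists were described by the median log2 ratio of their members with at least 10 CPM in the mean of both libraries, and by its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A percentile describes these 2 libraries and is not a test of the arms. The lists, the cell type markers, the rule for named genes and the alternatives except those said to be added were chosen before the data were examined. The genes named were genes chosen in advance (KDM1A, KLK3, KLK2, TMPRSS2, FKBP5, FOXA1, HOXB13, GATA2, MYC, MKI67, TOP2A and EZH2), the 15 highest and 15 lowest log2 ratios among genes at 50 CPM or more, and up to 2 highest and 2 lowest members of each list at 20 CPM or more. Mitochondrially encoded, ribosomal protein, Y-linked and clone-named genes and XIST were left out of the selection by size. DCN, LUM, COL1A1, COL1A2, COL3A1, EGFL7, HBB, FBXO28 and the genes named for empty droplets and shallow barcodes were chosen after their values were seen. Some genes and 2 lists chosen in advance are not reported here. Cluster-leading genes define the clusters and are not results.

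Alternatives covered the limits on UMIs and mitochondrial share, scaling by TMM (edgeR 4.0.16, R 4.3.3), median-of-ratios size factors, totals without mitochondrial and ribosomal protein genes, equal weight per cell, thinning, removal of free RNA at an assumed 10%, a pseudocount of 10 CPM, list minimums and cluster resolution. TMM and the size factors moved the median of all genes by -0.11 and -0.12 on the log2 scale. Added after the data were seen were runs without the 5% highest doublet scores, without cells under 3% mitochondrial UMIs, without the cluster led by DCN and LUM, with cells at or under the median of hypoxia list UMIs, and with cells under 10 UMIs of each cycle list.

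The ratio intervals were tested on simulated data of 9684 genes with 200 genes changed by known folds and counting error alone. For a planted fold of 2, 98.5% of intervals held it, and for a fold of 4, 93.5%. Of 200 simulated lists with no shift, 6.5% fell outside the central 95% of random lists, and 50 of 50 lists shifted by 0.5 fell above it. These lists held 25 genes with independent noise, so lists whose members vary together were not covered. Shifts smaller than 0.5 were not simulated. Neighbouring genes were taken from the RefSeq gene table of assembly GRCh38.p14, matched by symbol for 7068 of 7748 genes (91.2%). The build differs from that of the files, so no coordinates were used. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.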

Results

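Droplet-based single-cell RNA sequencing was carried out on LuCaP96, a patient-derived prostate cancer xenograft. The series title places the experiment in castration-resistant prostate cancer and names inhibition of the histone demethylase LSD1 and super-enhancer activity as its subject. The labels give 2 libraries, 1 named VEH and 1 named GSK, and do not spell out either name, a dose or a duration. The VEH library held 61768401 unique molecular identifiers (UMIs) and the GSK library 66813022. After cell calling 3944 VEH cells and 3533 GSK cells were kept, with a median of 11618.5 and 13833 UMIs and of 3124 and 3605 genes per cell. Mitochondrially encoded genes took 12.4% of the UMIs of kept VEH cells and 13.4% of those of GSK cells, and ribosomal protein genes 26.0% and 22.4%. Each group is 1 library, so no difference below has a replicate check, and every interval (95%) of a ratio or share covers counting error only. Intervals of list medians come from the order of the members and describe the spread among genes.

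The comparison of the GSK with the VEH library asks how transcription in the xenograft cells differed between the arms. Among genes at 50 CPM or more, the highest ratios of the GSK to the VEH library belonged to FN1, which encodes the matrix glycoprotein fibronectin, and PCA3, a prostate cancer-associated non-coding RNA. FN1 had 185 UMIs (3.62 CPM) in the VEH library and 89860 UMIs (1626 CPM) in the GSK library, a ratio of 449 (389 to 522). PCA3 stood at 6.06 and 332 CPM, a ratio of 54.8 (49.0 to 61.5). Interferon-stimulated genes were higher in the GSK library together, whereas MYC targets and S-phase genes were mostly lower. The median log2 ratio over the 7748 genes at 10 CPM or more was 0.07.

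Next to FN1 and PCA3, the highest ratios among genes at 50 CPM or more belonged to the metallothionein MT1E (9.39-fold, 8.56 to 10.3), the sphingolipid desaturase DEGS1 (5.36-fold), the protease inhibitor CSTA (4.89-fold), the antiviral GTPase MX1 (4.58-fold), IFI6 (3.84-fold) and NVL (3.63-fold). They were followed by IRF9, a component of the interferon-activated transcription factor ISGF3 (3.47-fold), RASGEF1A (3.42-fold), RAB31 (3.12-fold), GPRC5A (3.00-fold), FAM134B (2.88-fold), the galectin LGALS1 (2.87-fold) and TUBA1A (2.67-fold). At the other end, PSCA, a cell surface antigen of prostate cells, was 7.25-fold lower in the GSK library (6.69 to 7.87), with 90.1 CPM in VEH and 12.4 CPM in GSK cells. The syndecan SDC2 was lower by a ratio with an interval of 3.75 to 4.27, the retinol dehydrogenase RDH12 was 3.45-fold lower, the fatty acid binding protein FABP7 2.53-fold, APOD 2.45-fold and MAGEH1 2.09-fold. UGT2B15, which conjugates androgens, was 2.06-fold lower and the linker histone HIST1H1E 2.04-fold. With at most 10% mitochondrial UMIs the log2 ratio of PCA3 moved from 5.56 to 6.26, that of MT1E from 3.11 to 4.59, that of RDH12 from -1.74 to -0.79 and that of APOD from -1.26 to -0.40. ALB, ACADM, ITM2A, AIDA, MGAT4C, NPM1 and CRELD2 were between 1.61-fold and 1.81-fold lower. MT1E, TUBA1A, HIST1H1E, UGT2B15 and NPM1 have close copies in the genome, and their counts are uncertain to the extent that reads were divided among them.

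**Figure D1:**
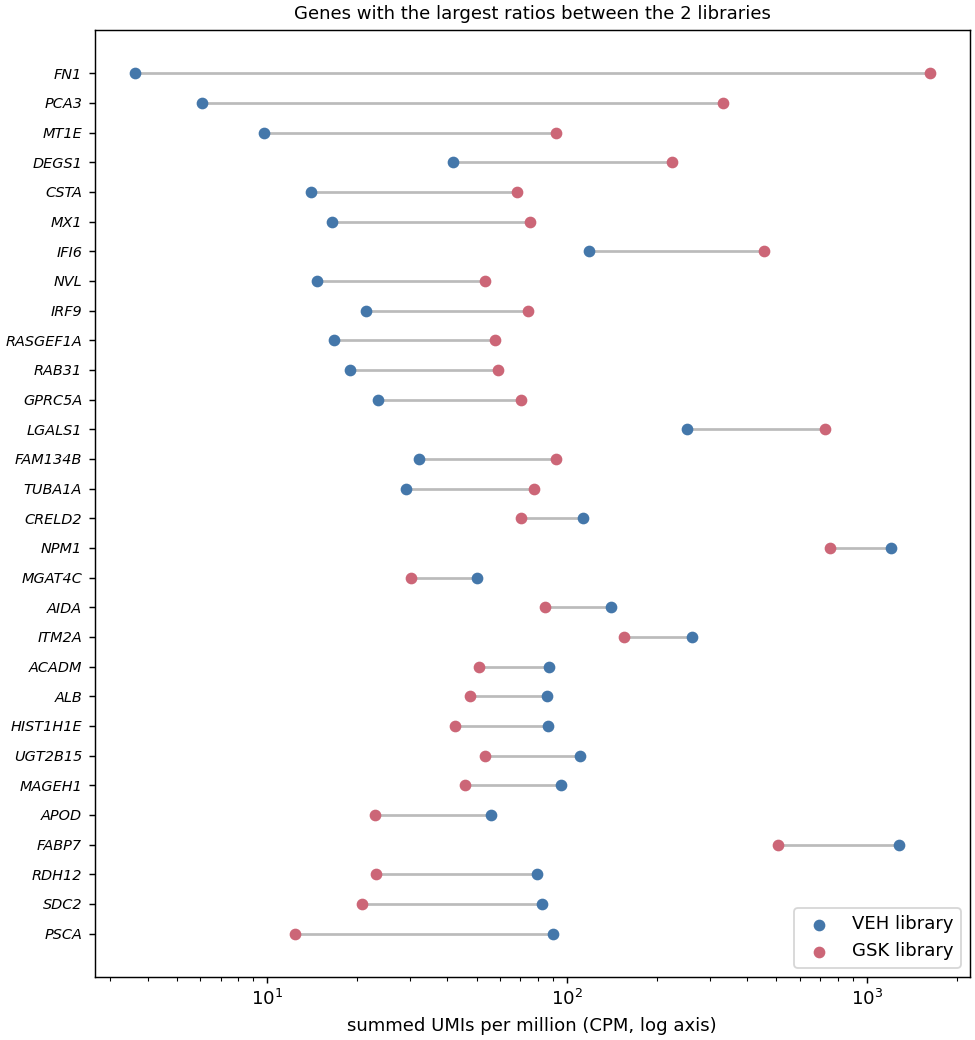
Summed counts in CPM (log axis) of the 15 genes with the highest and the 15 with the lowest ratio, for the VEH library (blue) and the GSK library (red), 1 library each. FN1 lies at 3.62 CPM in the VEH and 1626 CPM in the GSK library, and PSCA at 90.1 and 12.4 CPM.

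After thinning every cell to 6810 UMIs, an FN1 UMI was found in 1.32% of 3550 VEH cells (0.974 to 1.76%) and in 85.0% of 3384 GSK cells (83.7 to 86.2%). The corresponding shares for PCA3 were 2.06% (1.62 to 2.58%) and 68.0% (66.4 to 69.5%). Without thinning the FN1 shares were 2.10% and 89.4%. Barcodes of this depth made wholly of free RNA, with the profile of the empty droplets, would hold an FN1 UMI in 3.47% of VEH and nearly all GSK cases. Both shares found lay under these values, so the shares alone do not tell how many cells expressed FN1. For PCA3 the same expectation was 5.52% and 92.6%, above the shares found in both libraries. In the GSK library 69.9% of thinned cells held 3 or more FN1 UMIs. In the VEH library 10 cells did, the highest with 11. The most that free RNA could bring to VEH cells low in G2/M genes was a mean of 0.0085 FN1 UMIs.

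Single named genes expressed in prostate luminal cells differed in opposite directions, and TRPM4 was named for its high ratio. They do not give the direction of luminal genes as a set. The 12 luminal-like markers summed to 7718 CPM in the VEH and 7817 CPM in the GSK library. The kallikrein KLK2 (-0.38) and the immunophilin FKBP5 (-0.42) were lower in the GSK library on the log2 scale. The protease TMPRSS2 (0.41) and the cation channel TRPM4 (1.31) were higher. KLK3, which encodes prostate-specific antigen, stood at 2786 and 3004 CPM (0.11). This small difference changed sign with 2 of the 3 other scalings.

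Among the luminal and super-enhancer-linked transcription factors, 9 of 14 were higher in the GSK library and 5 lower, with a median of 0.13 (percentile 92.6). CREB3L1 (1.33), the epithelial factor ELF3 (0.56) and GATA2 (0.37) were higher, FOXA1 (0.19) and HOXB13 (0.12) differed little, and TBX3 (-0.21) and MYC (-0.53) were lower. MYC was low in both libraries, at 12.6 and 8.39 CPM. KDM1A, which encodes LSD1, was at 30.9 CPM in the VEH and 25.4 CPM in the GSK library (-0.27). The other LSD1 complex members included RCOR1 (0.26), HMG20B (0.29) and HDAC2 (-0.11). Of the 11 measured members, 9 were higher and 2 lower, with a median of 0.14 (percentile 77.4). Of 16 enhancer coactivators 14 were higher (median 0.13, percentile 84.7), among them BRD2 (0.36) and the nuclear receptor coactivator NCOA1, which was 2.29-fold higher. With median-of-ratios size factors the medians of all 3 lists were 0.01.

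Super-enhancer-dependent transcripts of cancer cells had a median of 0.35 over 9 measured genes (percentile 99.8), with 7 higher and 2 lower in the GSK library. The differentiation inhibitor ID2 (0.96) and SOX9 (0.87) were higher, CCND1 differed by 0.13, and MYC and ID3 (-1.26) were lower. The interval of this median from the order of its members ran from -0.53 to 0.87, so the members did not share a direction, and with no minimum level the median was 0.07.

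Among the lists with 3 or more measured genes, interferon-stimulated genes had the median farthest from 0. All 21 measured members were higher in the GSK library, with a median of 0.90 (percentile 100), and their summed level was 1515 CPM in the VEH and 3129 CPM in the GSK library. IFIT1, an interferon-induced RNA-binding protein, stood at 3.13 and 31.1 CPM, a ratio of 9.95 (8.46 to 11.8). The smallest differences among the named members belonged to IFITM2 (0.43) and IFI44 (0.46). Of 8 measured antigen presentation genes, 7 were higher, with a median of 0.48 (percentile 99.99). The interval of this median from the order of its members ran from -0.48 to 0.96, which is the whole range of the 8 genes. The summed level was lower in the GSK library (1686 and 1571 CPM). The peptide-loading factor TAPBP (0.96), the immunoproteasome subunit PSMB8 (0.77) and B2M (0.22) were higher, and the chaperone CALR was lower (-0.48). The interferon list had a positive median in all 5 classes of cells that held at least 100 cells of each library, from 0.70 in the S-phase cluster to 1.20 in the hypoxia cluster.

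MYC targets, here mostly nucleolar and ribosome biogenesis genes, had a median of -0.26 (percentile 0), with 24 of 26 lower in the GSK library. NPM1 (-0.68) and the mitochondrial chaperonin HSPD1 (-0.67) were lowest, while GNL3 (0.11) and WDR74 (0.15) were the 2 exceptions, and GNL3 changed sign with 2 other scalings. Within the hypoxia cluster the direction was the opposite, with a median of 0.15 and 17 of 26 genes higher in GSK cells. The cells of that cluster were not alike in the 2 libraries, since its GSK cells were lower in 17 of 18 hypoxia genes. In the S-phase cluster all 26 were lower (median -0.34).

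**Figure D2:**
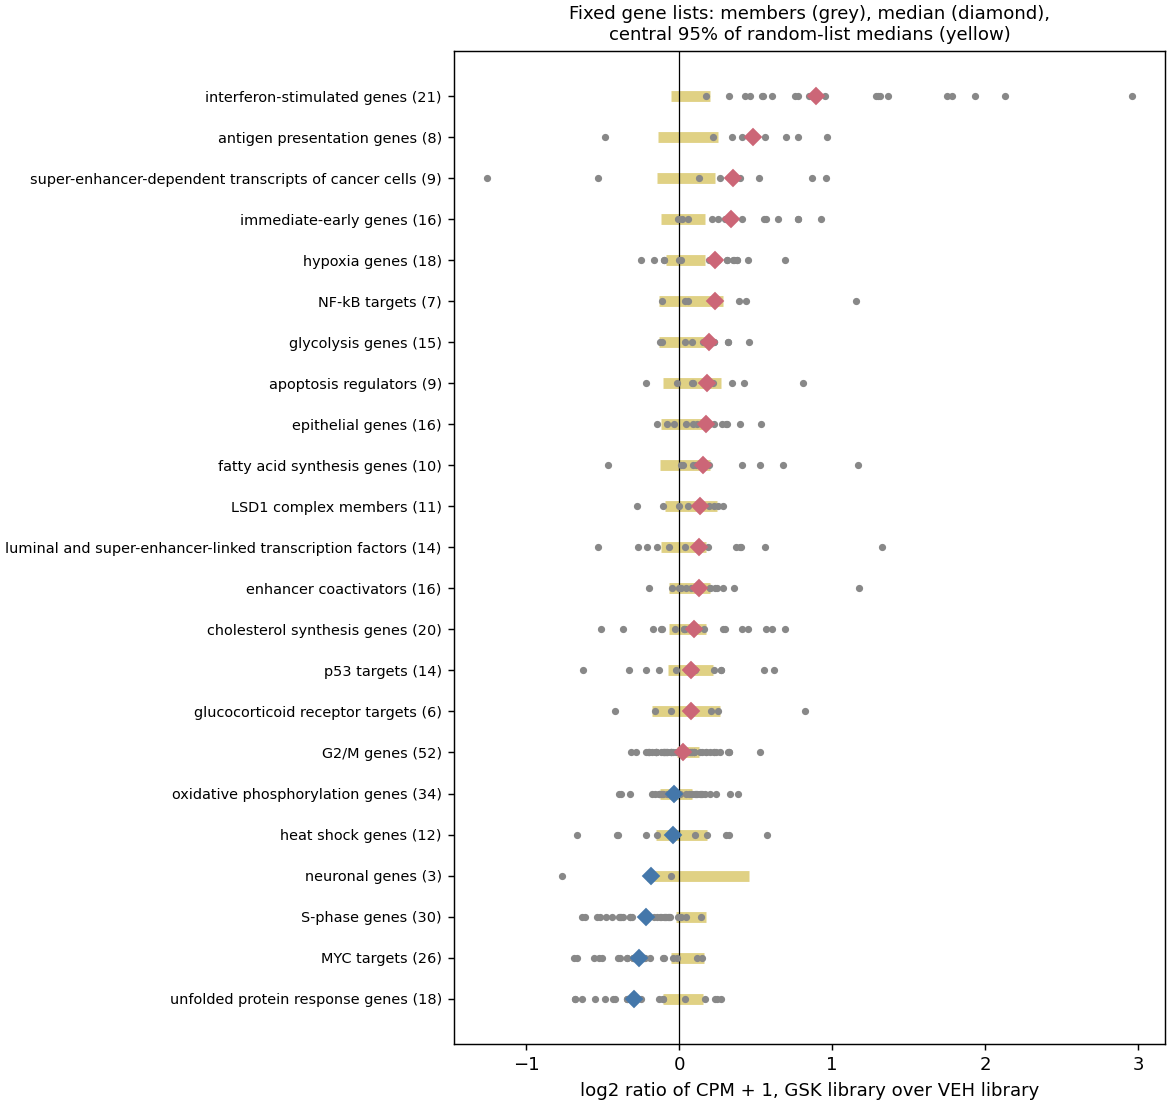
The gene lists described here with 3 or more measured members (number in brackets), 1 library per group. Grey points are members, diamonds the list median of the log2 ratio of CPM + 1 (GSK over VEH), and yellow bars the central 95% of medians of 10000 random lists. Interferon-stimulated genes lie at 0.90 and MYC targets at -0.26.

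S-phase genes had a median of -0.22 (percentile 0), with 27 of 30 lower in the GSK library. It was -0.42 without the cluster led by DCN and LUM, and 0.10, -0.12 and 0.04 within the hypoxia, S-phase and mitotic clusters, so the direction was not shared by all clusters. The replication licensing factor CDC6 (-0.64) and the primase PRIM1 (-0.61) were lowest, RFC2 was at 0.14, and USP1 was at 0.04, a value that changed sign under each other scaling. G2/M genes had a median of 0.03 (percentile 19.8, 27 higher and 25 lower), and its sign changed with scaling. The median was 0.43 in the S-phase cluster, with 51 of 52 genes higher in GSK cells, -0.01 in the mitotic cluster (25 higher and 27 lower) and -0.25 without the cluster led by DCN and LUM. ANP32E (0.53) and AURKB (0.32) were higher, CDK1 (-0.31) and UBE2C (-0.28) lower, and MKI67 (-0.02), TOP2A (-0.09) and EZH2 (-0.05) were near equality. At least 2 S-list UMIs were present in 94.5% of thinned VEH cells (93.7 to 95.3%) and 93.1% of GSK cells (92.2 to 93.9%), and 2 G2/M UMIs in 99.5% and 99.7%. Unthinned, the S-list shares were 97.0% and 98.2%. This limit was reached by nearly every cell, and free RNA of the same depth would carry 10.7 and 10.2 S-list UMIs and 31.3 and 40.5 G2/M UMIs. These shares were therefore read as background and not as cycling. With a limit of 10 UMIs, chosen after seeing the data, the S-list shares were 30.4% (28.9 to 31.9%) and 25.2% (23.8 to 26.7%), and the G2/M shares 65.9% (64.3 to 67.4%) and 69.0% (67.4 to 70.6%). The values given for free RNA are for barcodes made wholly of it, whereas cells low in G2/M genes held at most 24.2% and 23.6%. How much free RNA added to the shares at 10 UMIs was not tested.

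**Figure D3:**
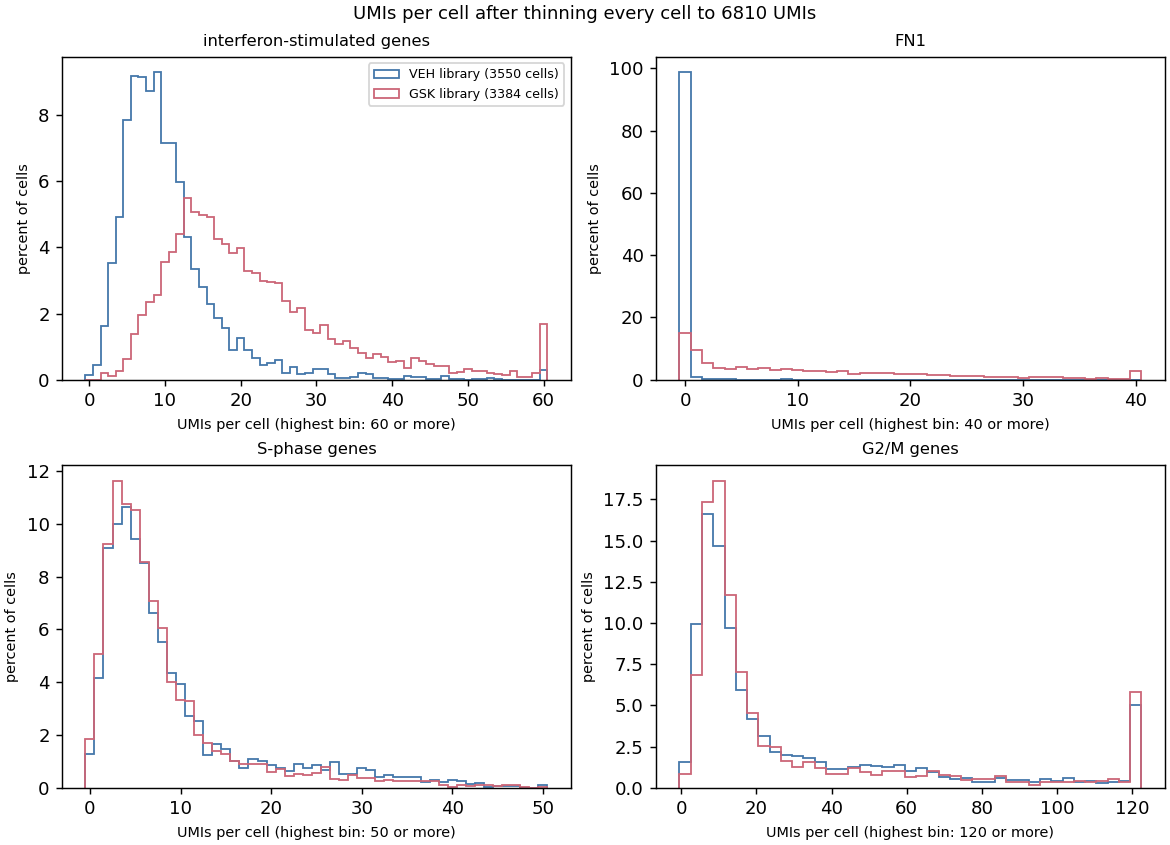
UMIs per cell after thinning to 6810 UMIs, as percent of cells, for interferon-stimulated genes, FN1, S-phase genes and G2/M genes, in 3550 VEH cells (blue) and 3384 GSK cells (red) of 1 library each. The highest bin collects all larger values. The median cell held 9 interferon list UMIs in the VEH and 18 in the GSK library.

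Unfolded protein response genes had a median of -0.30 (percentile 0), with 13 of 18 lower in the GSK library and an interval from the order of its members of -0.48 to 0.04. The endoplasmic reticulum proteins CRELD2 and MANF were both at -0.68, whereas DDIT3 (0.25) and TRIB3 (0.27), which belong to the stress response that acts through ATF4, were higher. With at most 10% mitochondrial UMIs the median moved to 0.00. Immediate-early genes were higher in 15 of 16 cases (median 0.34, percentile 100), led by ATF3 (0.93) and NR4A1 (0.78), with FOS (0.02) and KLF4 (0.00) near equality. Their median was 0.12 with at most 10% mitochondrial UMIs. Of 12 heat shock genes 5 were higher and 7 lower (median -0.04, percentile 23.7), with HSPB1 at 0.32, HSPA1A at 0.31, HSPH1 at -0.41 and HSPD1 at -0.67.

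Hypoxia genes had a median of 0.24 (percentile 99.9), with 14 of 18 higher in the GSK library. NDUFA4L2 (0.69) and the kinase PDK1 (0.45) were higher, and EGLN3 (-0.25) and ANGPTL4 (-0.10) lower. The hypoxia cluster held 218 VEH and 834 GSK cells, and another cluster with ANGPTL4, HILPDA and NDUFA4L2 among its leading genes held 796 VEH and 14 GSK cells. Within the hypoxia cluster the list median was -0.75, with 17 of 18 genes lower in GSK cells. It was -0.19 in the mitotic cluster (12 lower) and 0.34 in the S-phase cluster (17 higher). In cells under 10 UMIs of each cycle list it was 0.31 (13 higher), and in cells with 10 or more G2/M UMIs 0.29 (15 higher). Without the cluster led by DCN and LUM the hypoxia median was 0.05 and that of glycolysis genes 0.04. Glycolysis genes were higher in 13 of 15 cases (median 0.20, percentile 98.8), with ALDOC at 0.45, GPI at 0.32 and GAPDH at -0.11. Within the hypoxia cluster 12 of the 15 were lower (median -0.12), in the mitotic cluster 9 (-0.04) and in the S-phase cluster 2 (0.22). Oxidative phosphorylation genes were divided, 16 higher and 18 lower (median -0.03, percentile 35.3), with NDUFB1 at 0.38 and SDHC at -0.39. Cholesterol synthesis genes had a median of 0.10 (percentile 77.0), with ACAT2 at -0.37. In fatty acid synthesis 9 of 10 genes were higher (median 0.16, percentile 92.0), among them the elongase ELOVL5 (1.17) and the desaturase FADS1 (0.68), while ELOVL6 was lower (-0.47).

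Epithelial genes were higher in 13 of 16 cases (median 0.18, percentile 98.5), with the tight junction gene CLDN3 at 0.54, ST14 at 0.40 and KRT19 at -0.14. Of the mesenchymal list only FN1 reached 10 CPM. The neuroendocrine list had 1 measured gene, with a log2 ratio of 0.23, and the Wnt list 2, of which RNF43 was at -0.31. All 3 measured neuronal genes were lower in the GSK library (median -0.19, percentile 3.26), with VGF at -0.77 and RAB3A at -0.19. Of 7 NF-kB targets 6 were higher (median 0.23, percentile 94.3), led by NFKBIZ (1.16) and NFKB2 (0.44). p53 targets lay at 0.08 (percentile 55.1), with TP53INP1 at 0.62, BTG2 at 0.56, FDXR at -0.33 and GDF15 at -0.63. Glucocorticoid receptor targets were divided, 3 higher and 3 lower (median 0.07, percentile 64.5). Apoptosis regulators had a median of 0.18 (percentile 87.7), with MCL1 at 0.34 and BAX at -0.21. The medians of the p53, cholesterol and glucocorticoid lists changed sign with another scaling.

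The kept cells fell into 12 clusters, and between 11 and 12 of the 12 luminal markers were detected in each. Of these clusters 6 took more than 90% of their cells from a single library, together 52.9% of all cells, and may represent the libraries and not cell types. Clusters with at least 100 cells of each library were led by hypoxia genes (NDUFA4L2, ANKRD37 and ADM), by replication genes (RRM2, HELLS and MCM4) or by mitotic genes (ASPM, CCNB1 and CENPA). The FN1 difference was present within these 3 clusters, with ratios of CPM of 731 (285 to 2683), 543 (351 to 889) and 534 (346 to 875).

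Markers of other cell types were low in the kept cells. Macrophage-like markers summed to 3.32 CPM in the VEH and 2.97 CPM in the GSK library, and pericyte or smooth muscle-like markers to 6.22 and 9.41 CPM. Endothelial-like markers summed to 28.7 and 36.7 CPM, nearly all from EGFL7 alone (28.6 and 36.6 CPM). Basal-like markers summed to 1.68 and 2.12 CPM, neuroendocrine-like markers to 1.70 and 1.79 CPM, lymphocyte-like markers to 0.49 and 0.36 CPM, and neutrophil-like markers to 0 and 0.054 CPM. Erythroid-like markers summed to 0.23 and 7.20 CPM, the GSK value nearly all from HBB (7.13 CPM). Fibroblast-like markers reached 3 UMIs in 4.06% of thinned VEH cells (3.43 to 4.76%) and 0.207% of GSK cells (0.0832 to 0.426%). Their sum was 57.6 CPM and 29.9 CPM. Within that list DCN (22.3 and 0.49 CPM) and LUM (25.9 and 4.22 CPM) were higher in the VEH library, and the collagens COL1A1 (8.25 and 20.0 CPM) and COL3A1 (0.14 and 2.21 CPM) higher in the GSK library.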

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

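All tests in this part were chosen after the results were seen, except that of thinning, whose setting had been listed before. HBB, the beta-globin gene, stood at 303 CPM in empty droplets of the GSK library (1106 UMIs) and 12.1 CPM in those of the VEH library (42 UMIs), and drew attention because empty droplets were no part of the comparison. Kept cells held 7.13 and 0.039 CPM.

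Among barcodes between 1000 UMIs and the cell limit, which were also no part of the comparison, 29.4% of 1347 in the GSK library had under 3% mitochondrial UMIs (27.0 to 31.9%), against 11.3% of 1400 in the VEH library (9.68 to 13.1%). Those under 3% carried VIM at 952 CPM in the VEH and 524 CPM in the GSK library, APOE at 1684 and 843 CPM, TYROBP at 430 and 154 CPM and COL3A1 at 247 and 506 CPM, far above the kept cells. In them the interferon-stimulated genes ISG15 (406 and 1708 CPM) and IFI6 (79.6 and 433 CPM) were also higher in the GSK library, so the higher counts were not confined to the kept cells. Empty droplets held ISG15 at 517 and 1271 CPM and IFI6 at 115.7 and 404.2 CPM, and how much of it was free RNA in these barcodes was not tested. At least 3 macrophage-like marker UMIs were found in 2.36% of the VEH (1.63 to 3.29%) and 5.27% of the GSK barcodes in this range (4.14 to 6.60%).

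Interferon-stimulated genes were higher in the GSK library. At one depth the list median was 0.94, against an upper end of 0.20 for random lists. Sums scaled to their total hardly depend on depth per cell, so this could not test depth. Per cell, at that equal depth, the median was 9 list UMIs in the VEH and 18 in the GSK library. In cells low in 1 part of the G2/M list, the other part allowed at most 24.2% free RNA in the VEH and 23.6% in the GSK library. Less that most, these GSK cells held a mean of 17.4 list UMIs, against 10.5 in all for VEH cells, so free RNA does not account for it. Nor does a small subset, since 71.2% of them exceeded the median VEH cell plus that free RNA. A response to the treatment and a difference between 2 grafts cannot be told apart with 1 library per arm.

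FN1 and PCA3 were nearly confined to the GSK library. Host stromal cells would bring collagen with FN1, but the ratio of FN1 to COL1A2 was 1123 in the kept GSK cells, against 0.511 and 2.21 in the low-mitochondrial barcodes of the VEH and GSK libraries. Of the GSK cells low in G2/M genes, 59.4% held more FN1 UMIs than percentile 95 of the most free RNA could bring (55.9% to 59.4% over 4 limits on low), which argues against a small subset for FN1. Neither question was tested for PCA3. Its share of GSK cells (68.0%) lay under the 92.6% expected of barcodes made wholly of free RNA. Cells low in G2/M genes held at most 23.6% free RNA in the GSK library, and the PCA3 share expected at that level was not computed. Of the 10 VEH cells with 3 or more FN1 UMIs, 3 were in the largest GSK cluster and 2 held PCA3, and what they are was not resolved. Treatment and divergence of 2 grafts cannot be told apart with 1 library per arm.

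MYC targets were lower in the GSK library. A mix of cycling cells is argued against by medians of at most -0.13 in 4 classes of cells. These were the S-phase and mitotic clusters, cells under 10 UMIs of each cycle list, and cells with 10 or more G2/M UMIs. A mix of hypoxic cells could contribute: the median was -0.22 in cells at or under the hypoxia median, but 0.15 in the hypoxia cluster, whose cells differed in hypoxia genes between the libraries, so this stays open. Treatment and a difference between 2 grafts cannot be told apart with 1 library per arm.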

How the results depend on the processing

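No paired analysis was possible because each group is 1 library, and no replicate could be left out. Of 25 lists, 18 kept the sign of their median under all alternatives run, up to 19, of which 5 were chosen after seeing the data. The neuronal list ran 18 and was at 0 with no minimum level. All 84 named genes with a log2 ratio of at least 0.32 in size kept their sign under the 17 alternatives run for genes, and that limit was also set after seeing the data. Many of these genes were named for large ratios in the same data. Several alternatives could hardly turn a sign: a larger pseudocount cannot, and the scalings moved the median of all genes by -0.12 at most. Much of this count was therefore fixed in advance. G2/M genes changed sign under 8 alternatives, and the p53, oxidative phosphorylation, cholesterol, heat shock and glucocorticoid lists under 2 to 5. The median-of-ratios size factors brought the medians of luminal transcription factors, LSD1 complex members and coactivators to 0.01, 0.01 and 0.01. Keeping predicted doublets and all called cells changed nothing, as no cell had been removed. The planned set of non-cycling cells held 2 cells per library and was not used.

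MYC targets moved to -0.38 with TMM, -0.39 with size factors, -0.22 with a pseudocount of 10 CPM and -0.22 in cells at or under the hypoxia median. S-phase genes moved to -0.084 with members at 50 CPM or more and to -0.42 without the cluster led by DCN and LUM. In cells under 10 cycle list UMIs, a limit on the same genes, they moved to -0.047. That limit moved G2/M genes from 0.03 to 0.15. With at most 10% mitochondrial UMIs hypoxia genes were at 0.44 and immediate-early genes at 0.12, the latter at 0.21 with size factors. In cells under 10 cycle list UMIs the log2 ratios of RDH12, MT1E and IFIT1 were -2.64, 3.94 and 3.69. A pseudocount of 10 CPM brought FN1 to 6.91, PCA3 to 4.41, MT1E to 2.36, IFIT1 to 1.65 and PSCA to -2.16. The cause of these shifts was not tested, except that a larger pseudocount draws ratios toward 0.

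The S-list shares of VEH and GSK cells were 98.7% and 98.2% with 1 UMI, 85.5% and 83.9% with 3, 97.0% and 98.2% unthinned, and 30.4% and 25.2% with 10. With at most 10% mitochondrial UMIs the shares were 92.1% and 92.4%, so the order of the libraries turned there, as it did unthinned. The G2/M shares were 99.9% and 99.9% with 1 UMI, 98.4% and 99.2% with 3 and 65.9% and 69.0% with 10, and 99.97% of unthinned GSK cells passed. A limit of 10% mitochondrial UMIs left 987 VEH and 643 GSK cells. Resolution 0.25 gave 7 clusters, of which 1 took more than 90% of its cells from a single library (30.6% of all cells). At resolution 1 this held for 12 of 17 clusters (78.4% of all cells). Fewer UMIs per VEH cell limit the detection of low genes there.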

Other observations

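The test of neighbouring genes below was chosen after its result was seen. A small cluster of 28 VEH and 37 GSK cells was led by KLF10, C8orf4, CHAC1, SNHG12 and DDIT3. KLF10 stood at 895 CPM in it and 34.3 CPM in other cells.

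A pair of clusters shared RDH12, RBM3 and EBP among their 10 leading genes, although 1 held 263 VEH and 0 GSK cells and the other 44 VEH and 340 GSK cells. RDH12 was at 422 and 287 CPM in them.

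DEGS1 and NVL are neighbours in the RefSeq table, with FBXO28 on the other side of DEGS1. FBXO28 was 2.46-fold higher in the GSK library (2.27 to 2.67), DEGS1 5.36-fold and NVL 3.63-fold. The hypothesis that neighbouring genes share part of the difference between the libraries was tested over 7045 adjacent pairs of measured genes. Their log2 ratios had a rank correlation of 0.10, above the highest of 1000 permuted orders (0.04). The correlation is across genes, which are not independent replicates. It is weak, and may reflect overlapping transcripts as well as local regulation or a difference in gene dosage, none of which was separated.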
